A study of Mus musculus with 6 samples.

How the data were processed

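RNA was measured in marginal zone B cells, the splenic B cell subset that lies at the border of the white pulp, taken by flow sorting from the spleens of mice on the C57BL/6 background at 8 weeks of age. Per the labels, 3 libraries came from wild-type (WT) mice and 3 from mice with a conditional knockout (cKO) of CK2α, the catalytic subunit of the kinase CK2 that Csnk2a1 encodes. The Cre line, the deleted exons and the sort gates are not given in the sources used here, nor is any batch, sex or litter. The labels number the libraries of each group but do not say that each came from its own mouse, so a p-value measures the spread between these libraries, which may be technical in part.

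Per the labels' protocols, RNA was extracted with a spin-column kit and sent to a sequencing company. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.36 and STAR 2.5.2b, with the build mm9. The counting tool, the annotation, the strand setting and the normalization tool are not given in the sources used here. Of the 14864 Ensembl gene identifiers in the deposited table, 1190 have numbers that came into use only with later annotations than those of mm9, so the build behind the counts is uncertain and no coordinates are printed. Gene symbols came from GENCODE M21, which named 14808 of the identifiers and left 56 without a name.

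The deposited values are a signal per gene that the authors made by dividing read counts by a factor for each library, as the values show: every value was a whole multiple of what 1 read was worth, within 0.02 of a read, for 100.0% of the values in each library. In cKO replicate 1 the smallest value stood for 2 reads. Multiplying back gave 18778776, 19593997 and 21067977 reads for WT replicates 1, 2 and 3 and 23503756, 22005912 and 20054583 for cKO replicates 1, 2 and 3, whereas the deposited totals lay between 20608673 and 20951951. Each gene in the table had at least 61 recovered reads over the 6 libraries, so genes with fewer were not analysed here. A value of 1 read was 0.891 to 1.10 in the deposited unit. The 10 most abundant genes held 5.22% to 5.52% of each library. Pairs of libraries of one group differed by more than sampling noise, with a chi-square per gene of 6.37 to 12.7, so no library was counted as a repeat of another.

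The main test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(deposited value + 1), two-sided, with genotype as the only term, on the 14855 genes whose mean over the 6 libraries was at least 10. The 9 other genes were left out. Adjusted p values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. A log2 difference is always cKO minus WT on the log2(value + 1) scale, which understates the change of low genes, and ± after a log2 difference is its standard error. Deposited values are given as mean ± SD over 3 libraries. A gene is said to have risen or fallen only where it passed the threshold.

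Before the data were examined, 38 gene lists were fixed from textbook knowledge: 19 on B cell themes, 9 on general programmes, 8 of markers of other splenic cell types and 2 on library quality. Of their 761 genes, 669 were among the genes tested. Each list was tested with camera against all other genes, with a preset correlation between genes of 0.01, and its p was adjusted over the 38 lists. Camera with an estimated correlation was an alternative. Its adjusted p values tied at 0.675 for many lists whose unadjusted p values differed. Fry was also run, which asks another question, whether the genes of a list move on balance in one direction, and compares them with no other genes. Some genes stand in several lists, among them Klf2, Asb2, Myc, Bbc3, Fas and Ppp1r15a, so those lists are not independent.

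The genes named follow a rule fixed at the same time. They are the 3 CK2 subunit genes, and the 10 largest increases and 10 largest decreases past the threshold among genes with a mean of at least 100 in the higher group and no overlap between the 3 values of each group. Variable segments, uncharacterised Gm and Rik names, identifiers without a name and pseudogenes were left out of those 20. Immunoglobulin and T cell receptor constant genes were left out too, which the rule as fixed did not name. To these the rule adds up to 4 members past the threshold from each B cell or general list (those with the smallest adjusted p), and up to 3 members with the highest mean from each other list. Names outside the rule are marked where they appear. Without a stated strand setting, reads of overlapping genes cannot be told apart. Among the named genes this makes several uncertain, such as Rapgef4os3, which lies over Rapgef4, Jun with Junos, Ciita with Dexi, Pou2f1 with Cd247, Irf7 with Phrf1, Cd180 with Mast4, Gpr183 with Ubac2, Ppp1r15a with Tulp2, Bak1 with Ggnbp1, Bid with Bcl2l13, Mcm7 with Cops6 and Ap4m1, Nusap1 with Oip5, Wdr12 with Carf, Syvn1 with Mrpl49, Dvl2 with Acadvl, Pfkp with Pitrm1, Gapdh with Iffo1, Uqcrc2 with Pdzd9, mt-Nd5 with mt-Nd6, Foxp3 with Ccdc22 and Csnk2b with Gpank1, and others overlap noncoding or uncharacterised genes. Near-identical copies (Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Ighg2b and Ighg2c, Oas1a and its relatives) are uncertain too, since reads may map to more than 1 copy.

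On simulated counts for the 14689 genes of its step, drawn from the means and depths of these libraries, the same test called 56.2% of the genes changed 1.5-fold, 85.4% at 2-fold, 91.8% at 3-fold and 95.8% at 4-fold. It made 169 calls, of which 10 were false, and 2 calls when nothing was changed. A simulated list of 25 genes shifted 1.3-fold gave a camera p of 1.42e-22, and an unshifted list of 25 genes a p of 0.577. Each gene was drawn on its own there, so the simulated lists held no correlation between genes. In the real lists that passed, the estimated correlation ran from 0.0758 (T cell markers) to 0.581 (marginal zone markers). The simulation therefore does not check the camera p values of correlated lists. Its gene rates hold for its own setting, with 48 or 49 genes changed at each fold and no correlation between genes. In the real data 10.1% of the genes tested were called, at a median log2 size of 0.437.

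The other settings tried were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, rescaling by TMM, by quantiles and by the total without immunoglobulin genes, robust variance moderation, sample quality weights, the replicate number as a block, a log2 difference of at least 1, immunoglobulin and T cell receptor genes left out, each library left out in turn, and the count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 1473 genes and DESeq2 1630. A fit with the transcript length and GC trend removed, and a fit with a follicular score (the mean log2 value of Fcer2a and Ighd) as a covariate, were chosen after seeing the data. Shares of the deposited total were compared by an exact two-sided permutation test, whose smallest p with 3 libraries against 3 is 0.1.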

Results

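The transcriptomes of sorted splenic marginal zone B cells were compared between 3 libraries labelled WT and 3 labelled cKO, at 18778776 to 23503756 recovered reads each. The design asks how gene expression in these cells differs when the catalytic CK2α subunit has been deleted. The first principal component of the log2 values held 40.3% of the variance and separated the groups, with the WT libraries between -27.5 and -19.3 and the cKO libraries between 17.1 and 27.4. Each library correlated more closely with the other libraries of its group (0.9909 to 0.9933) than with the mean of the other group (0.9859 to 0.9886), across genes.

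The targeted gene was not lower in the libraries labelled cKO. Csnk2a1 (ENSMUSG00000074698), which encodes CK2α, stood at 3957 ± 105 normalised reads in WT and 4045 ± 87.6 in cKO (SD, n = 3 each). The log2 difference of 0.03 ± 0.05 did not pass the limma test (adjusted p = 0.734), and an exact permutation test gave p = 0.3, where 0.1 is the smallest it allows. The ratio of cKO to WT was 1.022, with a 95% interval of 0.947 to 1.104, so a fall of more than 5.33% lay outside the interval. Csnk2a2 (ENSMUSG00000046707), the gene of the other catalytic subunit, gave 1836 ± 71.7 and 1847 ± 28.5, and Csnk2b (ENSMUSG00000024387), that of the regulatory subunit, 1082 ± 98.3 and 1199 ± 59.6. Their log2 differences of 0.01 and 0.15 did not pass either (adjusted p = 0.941 and 0.239), and as a list the 3 subunit genes, none of them called, gave a camera adjusted p of 0.553. That of Csnk2a2 turned below 0 when the libraries were rescaled without immunoglobulin genes (-0.0057). A gene-level count does not resolve a deleted exon, so it could not show that the labels are right, and each direction below is that of the libraries as labelled.

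**Figure D1:**
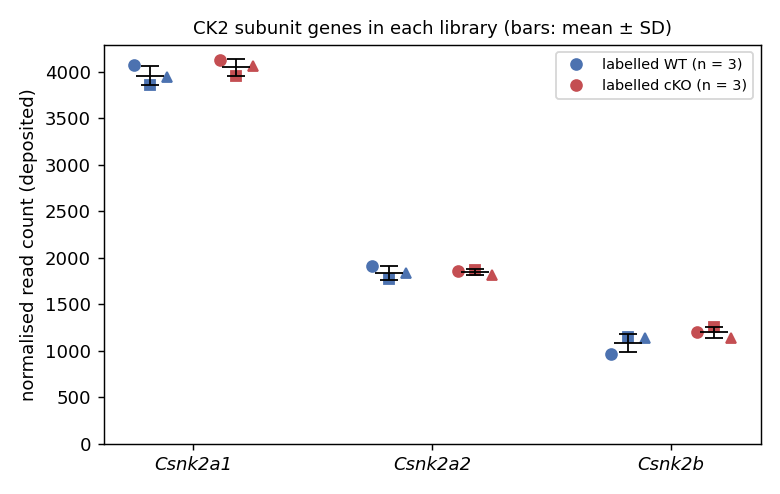
Normalised read counts of the 3 CK2 subunit genes (vertical axis, deposited unit) in each library labelled WT (blue) or cKO (red). Symbols are replicates 1 (circle), 2 (square) and 3 (triangle), and bars are mean ± SD; Csnk2a1 averaged 3957 in WT and 4045 in cKO.

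Of the 14855 genes tested, 755 rose and 739 fell in the libraries labelled cKO, together 1494 or 10.1%. Several of the largest increases under the naming rule were in genes barely expressed in WT. Flnc (ENSMUSG00000068699), a muscle filamin that crosslinks actin, went from 5.51 ± 3.01 to 135 ± 52.8 normalised reads, a log2 difference of 4.46 ± 0.42 (adjusted p = 0.000321). Ltbp4, which binds latent TGF-β, rose by 3.11 ± 0.26 and Slc12a5 (ENSMUSG00000017740), a neuronal potassium-chloride cotransporter, by 3.04 ± 0.22, the latter from 72.3 ± 8.56 to 628 ± 221. Prox1 (ENSMUSG00000010175), a homeobox factor of lymphatic endothelium, went from 14.5 ± 1.86 to 121 ± 4.39 (2.98 ± 0.21, adjusted p = 0.000109). The secreted glycoprotein gene Fstl1 followed at 2.87, then Dmwd at 2.28, its neighbour Dmpk, a muscle kinase gene, at 2.22, the hormone gene Stc1 at 1.99, the dopamine receptor gene Drd5 at 1.83 and Fam149a at 1.80.

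Among the decreases under the naming rule, Inpp4b (ENSMUSG00000037940), a phosphoinositide phosphatase, fell from 1370 ± 43.5 to 574 ± 50.9 normalised reads, a log2 difference of -1.26 ± 0.08 with the adjusted p of 3.38e-05. Mcoln2 (ENSMUSG00000011008), a cation channel of endosomes and lysosomes, fell from 986 ± 51.4 to 341 ± 67.0 (-1.55 ± 0.13, adjusted p = 0.000189). Sh2d2a, an adaptor protein of lymphocyte signalling, fell from 1021 ± 86.3 to 397 ± 58.5 (-1.37 ± 0.11). Antxr2, a receptor for anthrax toxin, gave -1.51, the drug efflux pump gene Abcb1b -1.45, the G protein subunit gene Gng12 -1.40, the noncoding gene Rapgef4os3 -1.33 and the semaphorin gene Sema5a -1.22. Hspa1a and Hspa1b, near-identical inducible heat shock genes, had the lowest log2 differences of the 10 (-2.54 ± 0.65 and -2.503 ± 0.65), with WT means of 378 ± 379 and 1439 ± 1464 that WT replicate 1 raised. Without that library they gave -1.71 and -1.64 and lost their call (adjusted p = 0.103 and 0.102, in a range of 0.00561 to 0.216 and 0.00395 to 0.232 over the alternatives), as they did without WT replicate 3 (0.104 and 0.11), cKO replicate 1 (0.0795 and 0.0861) or cKO replicate 3 (0.0692 and 0.0791), under robust moderation (0.216 and 0.232) and with the follicular score (0.0945 and 0.1). Gng12 gave 0.0619 without WT replicate 1 and 0.0658 without WT replicate 3, while the other genes of the 10 largest increases and decreases were called in every alternative.

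Most changes were small. The median size of the log2 difference among called genes was 0.437, while 137 genes rose and 76 fell by at least 1, 23 rose and 6 fell by at least 2, and 7 rose and 0 fell by at least 3. At an unadjusted p under 0.05, limma gave 3983 genes. The values of the groups did not overlap for 4687 genes, 31.6% of those tested, where chance gives 10%. The count of calls rested on several libraries. It was 510 without WT replicate 1, 497 without WT replicate 3, 927 without cKO replicate 1 and 531 without cKO replicate 3, and 811 with the follicular score as a covariate. Of the 113 called genes named by the rule, 53 missed the threshold without WT replicate 1, 17 without WT replicate 2, 56 without WT replicate 3, 31 without cKO replicate 1, 8 without cKO replicate 2 and 48 without cKO replicate 3. All 113 kept their direction there, but that was all but fixed in advance. The groups did not overlap for 1486 of the 1494 called genes, and leaving out a library cannot turn the direction of such a gene. Where genes are said to have lost a call, the highest adjusted p of these 5-library fits is given, with the library left out.

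**Figure D2:**
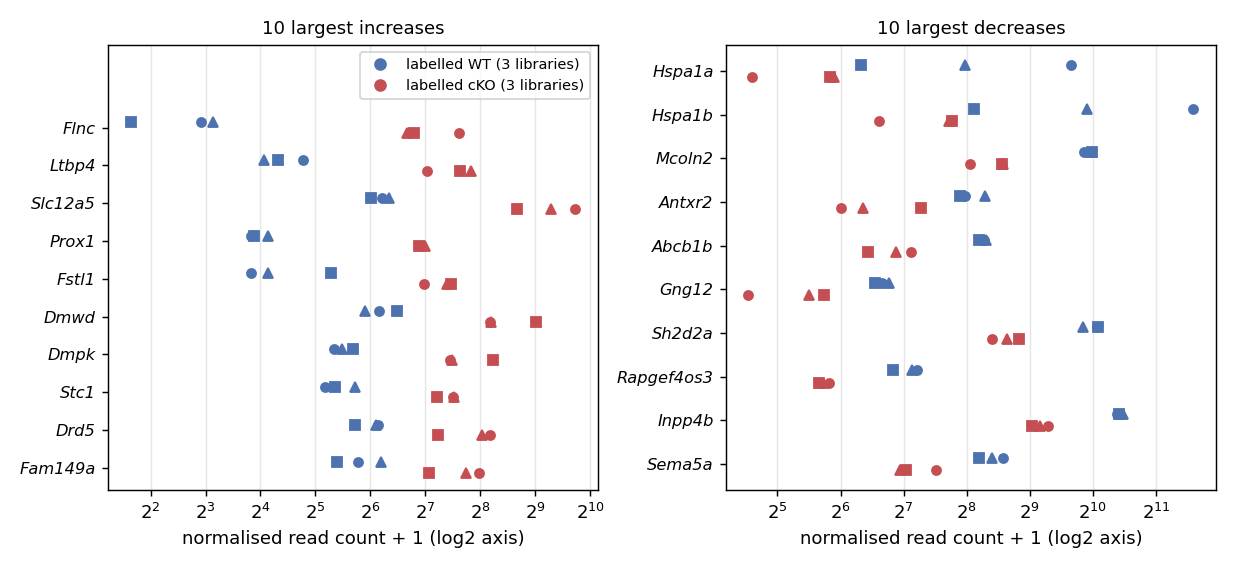
Normalised read counts plus 1 (horizontal log2 axis) of the 10 genes with the largest increases (left) and decreases (right) under the naming rule, one symbol per library (circle, square and triangle for replicates 1, 2 and 3; blue WT, red cKO). Flnc averaged 5.51 in WT and 135 in cKO, and the WT symbols of Hspa1a and Hspa1b are spread the widest.

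Interferon-stimulated genes rose together. Of the 33 measured members of the type I interferon list, 21 rose and 0 fell, and 28 rose and 1 fell when adjusted over the list alone. Irf7, a transcription factor that amplifies interferon production, went from 619 ± 44.5 to 1207 ± 190 normalised reads (log2 difference 0.95 ± 0.11, adjusted p = 0.000748). Oas2 and Oas1a, sensors of double-stranded RNA, rose by 1.12 ± 0.14 and 0.67 ± 0.08, and Rtp4 by 0.95 ± 0.12, and these 4 were called in every alternative. The median of the list was 0.42 (camera adjusted p = 1.49e-17), and adjusted p = 0.675 with an estimated correlation. In cKO replicate 1, Oas2 stood at 3058 against 1961 and 2001 in the other cKO libraries. Without that library the median of the list was 0.32.

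Of 22 genes of Toll-like receptor signalling 3 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0688). Tlr3, the endosomal receptor for double-stranded RNA, went from 817 ± 92.6 to 1891 ± 389 (1.19 ± 0.14, adjusted p = 0.000748), Tlr7, which senses single-stranded RNA, rose by 0.49 ± 0.11, and the adaptor gene Ticam1 by 0.33 ± 0.09. Cd180, a receptor homologue that regulates responses to lipopolysaccharide, fell by 0.43 on the log2 scale. The list passed without WT replicate 3 (0.0441), without cKO replicate 2 (0.0107) and with DESeq2 (0.0355), in a range of 0.0107 to 0.285, against adjusted p = 0.675 with an estimated correlation in all 6 libraries. Tlr7 lost its call without WT replicate 1 (0.102), and Cd180 and Ticam1 without WT replicate 3 (0.094 and 0.157).

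Immediate early genes, which are induced within minutes of stimulation and also during tissue dissociation, were lower in cKO. Of 25 measured, 16 fell and 0 rose, and 19 fell and 0 rose adjusted over the list alone. Jun, a subunit of the transcription factor AP-1, went from 14619 ± 1832 to 8234 ± 1558 normalised reads (-0.84 ± 0.13, adjusted p = 0.00402). Zfp36, which destabilises cytokine messages, fell from 13065 ± 2200 to 9743 ± 817 (-0.41 ± 0.11) and Myc from 12993 ± 1292 to 9580 ± 1801 (-0.45 ± 0.12). The median of the list was -0.56 (camera adjusted p = 2.77e-11), and adjusted p = 0.675 with an estimated correlation. Jun was called in every alternative, while Zfp36 and Myc lost their call (0.121 and 0.15, both without WT replicate 3), and Myc gave -0.29 without cKO replicate 2.

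Several NF-κB components and feedback targets fell too. Of 24 measured components and feedback targets, 6 fell and 0 rose (6 and 1 adjusted over the list alone). Tnfaip3, the ubiquitin-editing inhibitor A20, fell from 2536 ± 198 to 1804 ± 124 (-0.49 ± 0.07, adjusted p = 0.0034) and the subunit gene Rel by 0.44 on the log2 scale. Nfkbiz and Nfkbid gave -0.65 and -0.63. The list itself did not pass (median -0.02, camera adjusted p = 0.169), and Nfkbiz and Nfkbid lost their call without WT replicate 1 (0.0599 and 0.101). Among 26 JAK-STAT components and targets, 4 fell and 0 rose, also over the list alone: the receptor genes Il21r (-0.42) and Il4ra (-0.44), the kinase gene Pim1 (-0.42) and Stat4 (-0.29). That list gave an adjusted p of 0.143, and of 0.0436 without cKO replicate 2 (range 0.0436 to 0.414), against adjusted p = 0.675 with an estimated correlation in all 6 libraries. Its 4 genes lost their call, Il21r, Il4ra and Stat4 without cKO replicate 3 (0.0789, 0.121 and 0.139) and Pim1 without WT replicate 1 (0.144). Tnfaip3, Rel, Nfkbiz, Nfkbid, Pim1 and Stat4 had their lowest WT value in WT replicate 2, as Jun, Zfp36 and Myc did, while Il21r and Il4ra had their highest there. Irf4 and Ppp1r15a, given below, were also lowest there. Whether these falls are separate from that of the immediate early genes was not tested.

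Marker genes of marginal zone B cells were higher in cKO. Of 15 measured, 6 rose and 0 fell, and 7 rose and 0 fell adjusted over the list alone. Asb2, a ubiquitin ligase subunit, went from 1576 ± 146 to 3947 ± 1054 normalised reads (1.29 ± 0.16, adjusted p = 0.00126). The tetraspanin gene Cd9 rose from 1472 ± 56.6 to 2091 ± 193 (0.50 ± 0.07), Plac8 from 9312 ± 1131 to 13172 ± 1036 (0.50 ± 0.09) and Myof, a membrane-repair protein, from 7983 ± 79.8 to 11044 ± 1437 (0.46 ± 0.08). All of these kept their call in every alternative fit. The median of the list was 0.16 (camera adjusted p = 0.000634), and adjusted p = 0.675 with an estimated correlation. It was 0.10 without cKO replicate 3 and 0.0822 with the follicular score, and the list passed in both (0.0115 and 0.0223, in a range of 2.81e-07 to 0.0223).

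**Figure D3:**
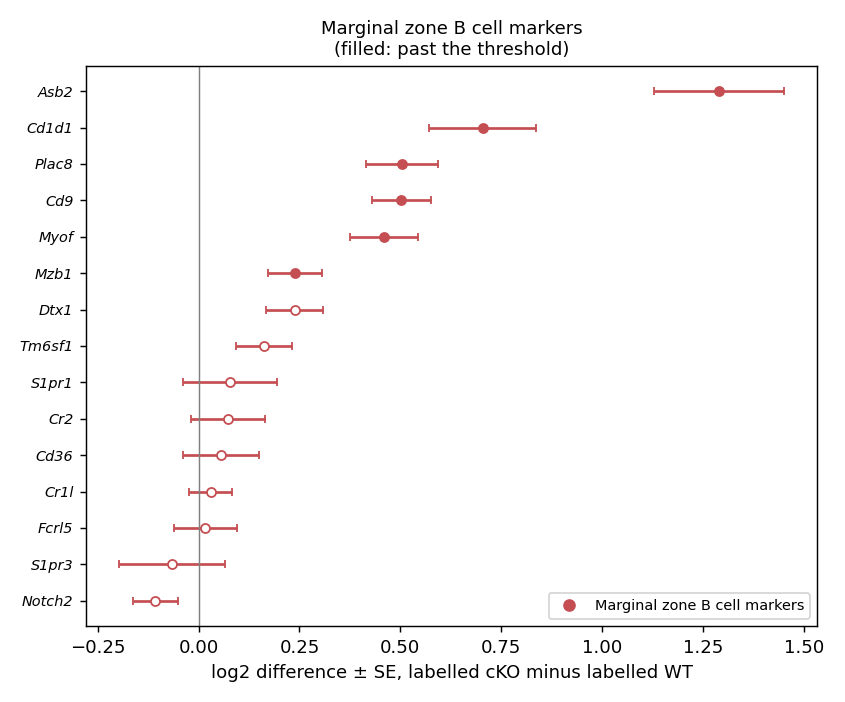
Log2 difference of each of the 15 marginal zone B cell markers, cKO minus WT (horizontal axis), with bars of 1 standard error; filled symbols passed the threshold. Of these 6 rose, led by Asb2 at 1.29, and 0 fell.

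Marker genes of follicular B cells, the main splenic subset, were lower. Of 7 measured, 3 fell and 0 rose, and 4 fell and 1 rose adjusted over the list alone. Klf2, a transcription factor of lymphocyte quiescence and trafficking, fell from 7005 ± 562 to 5054 ± 705 (-0.48 ± 0.09, adjusted p = 0.0117), and Ccr7, the receptor that guides cells towards the T zone, from 2957 ± 171 to 2076 ± 599 (-0.55 ± 0.15). The median was -0.42 (camera adjusted p = 0.0275), and adjusted p = 0.675 with an estimated correlation. The call was lost without WT replicate 2 (0.0795), cKO replicate 1 (0.0721, median -0.27) or cKO replicate 3 (0.109), under robust moderation (0.113) and with the follicular score (0.285, median -0.0641), in a range of 1.15e-05 to 0.285. Klf2 lost its call without WT replicate 3 (0.0625) and Ccr7 without cKO replicate 3 (0.14). The follicular score, centred over the libraries, was 0.14, 0.31 and 0.21 in WT replicates 1, 2 and 3 and -0.63, 0.43 and -0.47 in cKO replicates 1, 2 and 3, so cKO replicate 2 lay above each WT library.

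Genes of the Notch pathway, whose receptor Notch2 directs marginal zone fate, went both ways. Of 28 receptors and machinery genes, 5 fell and 1 rose (8 and 2 adjusted over the list alone). Notch1 fell from 968 ± 57.6 to 710 ± 30.9 (-0.45 ± 0.07, adjusted p = 0.00481), the glycosyltransferase gene Mfng gave -0.29, and the coactivator genes Maml3 and Maml2 gave -0.73 and -0.27 (camera adjusted p = 0.169 for the list). Mfng lost its call without cKO replicate 3 (0.0838), Maml3 without WT replicate 1 (0.108) and Maml2 without WT replicate 3 (0.115). Among 12 Notch targets, 2 rose and 1 fell (4 and 1 over the list alone). Heyl, a repressor induced by Notch, went from 19.3 ± 6.21 to 97.1 ± 17.8 (2.30 ± 0.26, adjusted p = 0.000756), Asb2 rose as above, and Myc fell. The target list gave an adjusted p of 0.143, but 0.0283 with edgeR and 0.0421 with DESeq2 (range 0.0283 to 0.273), against adjusted p = 0.675 with an estimated correlation in all 6 libraries.

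Germinal centre genes were lower. Of 12 measured, 3 fell and 0 rose, and 7 fell and 1 rose adjusted over the list alone. Bcl6, the repressor that drives the germinal centre programme, went from 812 ± 233 to 414 ± 129 (-0.97 ± 0.22, adjusted p = 0.0214), Nuggc from 85.8 ± 30.6 to 38.9 ± 6.26 (-1.08 ± 0.26) and the death receptor gene Fas from 84.2 ± 22.2 to 43.1 ± 8.70 (-0.94 ± 0.24). The median was -0.68 (camera adjusted p = 0.0116), and adjusted p = 0.688 with an estimated correlation. Without cKO replicate 3 the list gave 0.0712 and with the follicular score 0.148, in a range of 0.000324 to 0.148, and without WT replicate 1 Bcl6, Nuggc and Fas lost their call (0.0899, 0.104 and 0.136). Of 8 genes of immature and transitional B cells, Vpreb3, which acts in assembly of the B cell receptor, rose (0.51 ± 0.13; adjusted p = 0.101 without WT replicate 1) and none fell, with the same counts over the list alone (camera adjusted p = 0.319, but 0.0187 without cKO replicate 1 and 0.0101 with the follicular score, in a range of 0.0101 to 0.96, against adjusted p = 0.715 with an estimated correlation in all 6 libraries). Of 18 genes of B1 and age-associated B cells, the repressor gene Bhlhe41 fell (-0.64 ± 0.16; adjusted p = 0.121 without WT replicate 3, log2 difference -0.43 without cKO replicate 1) and none rose, against 5 and 1 over the list alone (camera adjusted p = 0.275).

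In B cell receptor signalling, 2 of 35 genes rose and 4 fell (2 and 5 adjusted over the list alone). Cd81, a tetraspanin gene, rose from 4029 ± 212 to 5865 ± 432 (0.54 ± 0.07, adjusted p = 0.00111) and the adaptor gene Dapp1 by 0.23. Rasgrp3, an activator of Ras, fell from 3969 ± 348 to 2273 ± 399 (-0.81 ± 0.11, adjusted p = 0.00184), and Fcgr2b, the inhibitory Fc receptor, from 5472 ± 270 to 4184 ± 226 (-0.39 ± 0.06). The list did not pass (camera adjusted p = 0.373), and Dapp1 lost its call without WT replicate 3 (0.0815).

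Of 27 genes of the PI3K, AKT and FoxO axis, 7 fell and 2 rose (9 and 2 adjusted over the list alone). Irs2, an insulin receptor substrate, fell from 1720 ± 325 to 975 ± 134 (-0.81 ± 0.13), Tsc1, an inhibitor of mTORC1, by 0.38 on the log2 scale, and Klf2 as above, whereas the stress-induced gene Sesn1 rose from 4373 ± 493 to 6620 ± 978 (0.59 ± 0.10, adjusted p = 0.00725). The median was -0.11 (camera adjusted p = 0.0163), and adjusted p = 0.675 with an estimated correlation. Among 31 B cell transcription factors, 7 fell and 1 rose (13 and 2 over the list alone). Pou2f1 fell from 3031 ± 60.1 to 2246 ± 188 (-0.44 ± 0.07), Foxo1 by 0.32 on the log2 scale, and Id2, an inhibitor of E proteins, rose from 600 ± 21.2 to 945 ± 211 (0.63 ± 0.13). Without WT replicate 3 Klf2, Foxo1 and Id2 lost their call (0.0625, 0.0783 and 0.0639). The median was -0.09 (camera adjusted p = 0.0129), and adjusted p = 0.675 with an estimated correlation. The log2 difference fell with transcript length (Spearman -0.167 across 11287 genes, which are not independent replicates). With that trend removed neither list passed (0.176 for both), at medians of -0.0815 and -0.0694. Nor did they with the follicular score (0.0904 and 0.113), at medians of -0.0855 and -0.0589. The transcription factors also lost their call without cKO replicate 1 (0.0812), their median was -0.15 without cKO replicate 2, and the ranges were 0.00289 to 0.176 and 0.00138 to 0.176.

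**Figure D4:**
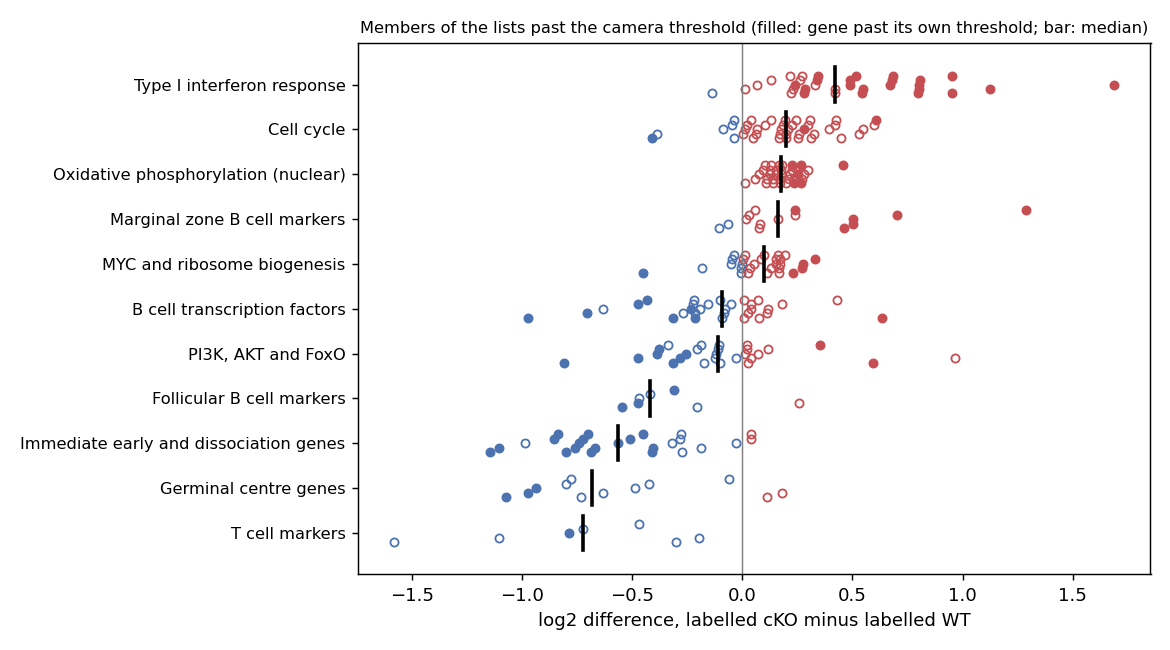
Log2 difference of each measured gene, cKO minus WT (horizontal axis), in the 11 lists past the camera threshold; filled symbols are genes past their own threshold, red above 0 and blue below, and black bars are list medians. Medians ran from -0.72 for T cell markers to 0.42 for the type I interferon response.

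Genes of antibody-secreting cells changed in both directions. Of 13 measured, 3 fell and 2 rose (5 and 2 adjusted over the list alone). Irf4, a factor needed for plasma cell differentiation, fell from 9404 ± 2381 to 5663 ± 892 (-0.71 ± 0.16, adjusted p = 0.0237), Slamf7 gave -0.53 and Zbtb38 -0.26, and Edem1, which acts in disposal of misfolded glycoproteins, rose by 0.27 (camera adjusted p = 0.352). Irf4 lost its call without WT replicate 1 (0.104), Edem1 without cKO replicate 3 (0.12) and Zbtb38 without WT replicate 3 (0.155). Among 11 immunoglobulin constant genes, Ighg3 rose from 534 ± 25.5 to 903 ± 203 (0.73 ± 0.14, adjusted p = 0.0107), while Ighg2c fell from 97.4 ± 70.2 to 24.9 ± 5.75 (-1.72 ± 0.41) and Ighg2b from 421 ± 61.7 to 252 ± 83.2 (-0.77 ± 0.19). These lost their call without WT replicate 3 (0.0517, Ighg3), cKO replicate 3 (0.0766, Ighg2c) and WT replicate 1 (0.132, Ighg2b). Adjusted over the list alone 3 rose and 4 fell. Its median was 0.0015, its mean -0.30 and its camera direction down (adjusted p = 0.954). All immunoglobulin genes together held 1.065% ± 0.063 of the WT signal and 1.048% ± 0.045 of the cKO signal (SD, n = 3 each; exact permutation p = 0.9).

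The unfolded protein response split. Of 30 genes 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.997). Asns, which makes asparagine, went from 42.7 ± 6.99 to 112 ± 29.7 (1.36 ± 0.22, adjusted p = 0.00566) and the chaperone gene Pdia4 from 22990 ± 889 to 31867 ± 4312 (0.46 ± 0.09). Ppp1r15a, which restores translation after stress, fell from 8647 ± 883 to 5834 ± 370 (-0.56 ± 0.08) and Syvn1, a ligase of endoplasmic reticulum degradation, by 0.34 on the log2 scale. Of 20 heat shock and chaperone genes, Hspb1 rose (1.47 ± 0.32) from 14.6 ± 5.14, and Hspa1a and Hspa1b fell, with 2 up and 4 down over the list alone. The median was 0.02, the mean -0.18 and the camera direction up (adjusted p = 0.997). WT replicate 1 held the highest value among the WT libraries for 19 of the 20, and without it the list rose, with a median of 0.20 (adjusted p = 0.000203, range 0.000203 to 0.998), against adjusted p = 0.999 with an estimated correlation in all 6 libraries. Pdia4 lost its call without cKO replicate 3 (0.0606) and Hspb1 without WT replicate 3 (0.0593).

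Nuclear genes of oxidative phosphorylation were slightly but evenly higher. All 35 measured had a log2 difference above 0, 6 rose and 0 fell, and 16 rose adjusted over the list alone. Uqcrc2 of complex III rose from 1906 ± 116 to 2289 ± 37.0 (0.27 ± 0.06, adjusted p = 0.0209), Atp5b of ATP synthase from 9604 ± 561 to 11270 ± 203 (0.23 ± 0.06), and the complex I genes Ndufa1 and Ndufa9 by 0.46 and 0.26. The median was 0.17 (camera adjusted p = 1.78e-09), and adjusted p = 0.675 with an estimated correlation. With the length trend removed the median was 0.13 (camera adjusted p = 2.15e-06 at the preset correlation). Uqcrc2 and Atp5b lost their call without WT replicate 3 (0.086 and 0.0968), and Ndufa1 and Ndufa9 without WT replicate 1 (0.0959 and 0.129). Of 12 genes of the mitochondrial genome none passed, also over the list alone (camera adjusted p = 0.143). The values were 187833 ± 8038 and 204380 ± 4582 for mt-Co1, 69305 ± 3318 and 77450 ± 2182 for mt-Cytb, and 56342 ± 2263 and 56975 ± 536 for mt-Nd5. The log2 difference of mt-Co1 was 0.12, and -0.02 with quantile scaling. Mitochondrial genes held 2.147% ± 0.080 of the WT signal and 2.296% ± 0.044 of the cKO signal (exact permutation p = 0.1, the smallest possible). In glycolysis 4 of 22 genes rose and 3 fell (6 and 4 over the list alone; camera adjusted p = 0.373), with Pgk1, Gapdh and Gpi1 at 0.31, 0.25 and 0.21 and the phosphofructokinase gene Pfkp at -0.34. Pfkp was called in every alternative, whereas Pgk1 and Gapdh lost their call without cKO replicate 3 (0.0665 and 0.0868) and Gpi1 without WT replicate 3 (0.104).

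The cell cycle list and the list of MYC targets and ribosome biogenesis had medians slightly above 0, with few members past the threshold. Of 40 cell cycle genes 2 rose and 1 fell, also over the list alone: Nusap1, a spindle protein, from 294 ± 45.6 to 448 ± 60.4 (0.61 ± 0.13, adjusted p = 0.0195), the replicative helicase gene Mcm7 by 0.28, and the licensing factor gene Cdt1 at -0.41. The median was 0.20 (camera adjusted p = 0.00322), and adjusted p = 0.694 with an estimated correlation. Of 29 genes of MYC targets and ribosome biogenesis 4 rose and 1 fell, again with the same counts over the list alone. The nucleolar genes Npm1 (13531 ± 913 to 17011 ± 941), Ncl, Nop58 and Wdr12 rose by 0.33, 0.23, 0.28 and 0.27, while Myc fell. The median was 0.10 (camera adjusted p = 0.0194), and adjusted p = 0.694 with an estimated correlation. Cell cycle lost its call without cKO replicate 2 (0.091) or cKO replicate 3 (0.0712, median 0.13), and its median was 0.32 without cKO replicate 1, with a range of 2.1e-11 to 0.091. The MYC list lost it without WT replicate 3 (0.0836), without cKO replicate 1 (0.271, median -0.0066) and with the follicular score (0.247), with a range of 0.00537 to 0.271. The genes named here lost their call too, Nusap1 and Npm1 without cKO replicate 3 (0.0779 and 0.0566), Mcm7, Cdt1 and Nop58 without WT replicate 1 (0.0783, 0.122 and 0.0783), and Ncl, Wdr12 and Myc without WT replicate 3 (0.106, 0.12 and 0.15).

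Of 24 genes of B cell survival 3 rose and 3 fell (4 and 3 adjusted over the list alone). Bak1, a mitochondrial death effector, rose from 1134 ± 40.0 to 1533 ± 36.5 (0.44 ± 0.06, adjusted p = 0.00198). Bid rose from 2490 ± 107 to 3397 ± 276 (0.45 ± 0.07), and Bbc3, which encodes PUMA, from 150 ± 16.8 to 231 ± 21.7 (0.62 ± 0.13). Cflar, an inhibitor of caspase activation, fell by 0.25 on the log2 scale. The list did not pass, with a median of 0.02, a mean of -0.0035 and camera up (adjusted p = 0.553). Of 17 p53 targets 2 rose and 2 fell, also over the list alone: Ccng1 (0.47 ± 0.07) and Bbc3 rose, Plk2 (-0.97 ± 0.18) and Fas fell. The median was 0.10, the mean -0.0024 and camera up (adjusted p = 0.453). Of 16 Wnt genes 1 rose and 1 fell (3 and 3 over the list alone): Fzd6, a Wnt receptor, from 7.94 ± 1.19 to 29.0 ± 14.5 (1.62 ± 0.41), and Dvl2 at -0.40. There the median was 0.0046, the mean 0.10 and camera down (adjusted p = 0.997). Bak1, Bid, Ccng1 and Plk2 were called in every alternative, while Bbc3 and Cflar lost their call without WT replicate 3 (0.0682 and 0.112), Fas and Dvl2 without WT replicate 1 (0.136 and 0.0795) and Fzd6 without cKO replicate 3 (0.137).

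Several homing receptor genes fell. Of 30 migration and adhesion genes 6 fell and 1 rose (9 and 7 adjusted over the list alone). Cxcr4, the receptor for CXCL12, fell from 6674 ± 681 to 4686 ± 954 (-0.52 ± 0.12, adjusted p = 0.0232), Ccr6 gave -0.47 and Gpr183, the oxysterol receptor that positions B cells, -0.40. Ackr2, a scavenging chemokine receptor, rose from 1398 ± 86.8 to 2278 ± 440 (0.69 ± 0.12, adjusted p = 0.00736), and the list did not pass (camera adjusted p = 0.588). Of 25 antigen presentation and costimulation genes 4 fell and 1 rose, also over the list alone. Ciita, the master regulator of MHC class II, fell from 8078 ± 276 to 6323 ± 383 (-0.35 ± 0.06, adjusted p = 0.00583), the ligand genes Pdcd1lg2 and Icosl gave -0.71 and -0.28, and the costimulatory ligand gene Cd80 rose by 0.82 ± 0.20, to 122 ± 34.8. That list gave an adjusted p of 0.143, and passed without WT replicate 1 (0.0214), with the length trend removed (0.0343) and with DESeq2 (0.0474), in a range of 0.0214 to 0.256, against adjusted p = 0.694 with an estimated correlation in all 6 libraries. Ackr2, Ciita and Pdcd1lg2 were called in every alternative, while Cxcr4 lost its call without WT replicate 1 (0.102), Ccr6 and Icosl without cKO replicate 3 (0.0775 and 0.096), and Gpr183 and Cd80 without WT replicate 3 (0.0908 and 0.1).

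Markers of other splenic cells were measured beside these. T cell markers were lower: each of the 7 had a log2 difference below 0 and Lck, a kinase of T cell receptor signalling that some B cells also express, fell from 631 ± 49.2 to 369 ± 71.5 (-0.79 ± 0.13, adjusted p = 0.00534). Foxp3 (39.2 ± 7.79 and 31.7 ± 7.02) and Lat (33.4 ± 5.33 and 24.0 ± 4.73) did not pass. Adjusted over the list alone 3 fell and 0 rose, with a median of -0.72 (camera adjusted p = 0.0116), and adjusted p = 0.675 with an estimated correlation. With a mean of at least 50 required, Lck stood alone (adjusted p = 0.0975, range 0.00492 to 0.0975). Of 6 NK cell markers the cytokine receptor gene Il2rb fell from 143 ± 16.6 to 73.6 ± 23.9 (-0.99 ± 0.22) and none rose, also over the list alone, with Prf1 at 0.29 and Ccl5 at 0.13, neither of them past the threshold (camera adjusted p = 0.88). Il2rb lost its call without WT replicate 3 (0.0896).

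Myeloid markers gave few calls. Of 23 monocyte and macrophage markers the adaptor gene Tyrobp rose from 560 ± 32.6 to 778 ± 30.6 (0.47 ± 0.07, adjusted p = 0.00452) and none fell, also over the list alone, with Lyz2 at 0.10 and Adgre1 at -0.05, neither past the threshold. That list gave a median of -0.48 and an adjusted p of 0.342, but passed downward without cKO replicate 1 (0.000772, median -0.86) and with the follicular score (0.0244, median -0.84), in a range of 0.000772 to 0.953, against adjusted p = 0.93 with an estimated correlation in all 6 libraries. Of 6 dendritic cell markers the transcription factor gene Zbtb46 rose from 49.4 ± 13.2 to 94.4 ± 7.82 (0.95 ± 0.23) and none fell, also over the list alone, with Flt3 at -0.45 and Itgax at -0.13 not past the threshold. The median was -0.03, the mean 0.08 and camera down (adjusted p = 0.997). Zbtb46 lost its call without WT replicate 3 (0.0797), and Flt3 passed without cKO replicate 1 (0.0276, log2 difference -0.71). None of 6 neutrophil markers passed, also over the list alone (Csf3r -0.05, Ngp -0.71, S100a9 -0.64), with a median of -0.14, a mean of -0.01 and camera up (adjusted p = 0.997).

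None of 14 erythroid markers passed, also over the list alone, with log2 differences of -0.40 for Hbb-bs, -0.21 for Hba-a1 and -0.25 for Hba-a2. There the median was -0.09, the mean -0.04 and camera up (adjusted p = 0.997), and globin genes held 0.0204% ± 0.0273 of the WT signal and 0.0109% ± 0.0104 of the cKO signal (exact permutation p = 0.8). Of 5 platelet markers (Itgb3 -0.16, Gp1ba 0.34, Itga2b -0.72) and 5 stromal and endothelial markers (Pecam1 0.06, Cdh5 0.37, Sparc -0.28) none passed, also over each list alone, with camera adjusted p values of 0.88 and 0.934.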

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

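The fits with the length and GC trend removed or with the follicular score were chosen after seeing the data. All 113 called genes named kept their direction in each of the 20 alternative fits that tested them, and 52 were past the threshold in each fit. None of the 1494 called genes changed sign in a fit that tested it. The groups of 1486 of them do not overlap, and leaving out a library cannot turn the sign of such a gene, so the directions kept in those fits are no sign of robustness. The fit with a mean of at least 50 has no value for lower genes, Hspb1 and Fzd6 among them. The named genes that lost their call numbered 0 to 4 under the pseudocounts, filters, scalings, sample weights, block and count tests, 14 under robust moderation, 5 with the length trend removed, 37 with the follicular score, and 53, 17, 56, 31, 8 and 48 without WT replicates 1, 2 and 3 and cKO replicates 1, 2 and 3, where fewer libraries and degrees of freedom remain. Of the named genes not called, Itga2b passed with sample weights (adjusted p = 0.0491), Flt3 and Itga2b without cKO replicate 1 (0.0276 and 0.0385) and Prf1 without cKO replicate 2 (0.0437), in ranges of 0.0385 to 0.249 (Itga2b), 0.0276 to 0.422 (Flt3) and 0.0437 to 0.615 (Prf1). Csnk2a1 missed the threshold in each fit, with log2 differences between 0.0045 and 0.052.

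Over the fits without one library the number of genes ran from 497 to 1730, with 247 to 787 higher and 221 to 943 lower. It was 811 (394 higher, 417 lower) with the follicular score and 213 (137 and 76) at a log2 difference of at least 1. edgeR shared 1429 of its 1473 genes with the main test and DESeq2 1380 of 1630. Same-numbered libraries of the groups deviated with correlations of -0.0745, -0.02 and 0.147. The libraries numbered 3 deviated most like each other, while those numbered 1 and 2 did not. These values give no clear sign that the numbers pair the libraries, but so few libraries cannot exclude it. With the replicate number as a block 1551 genes passed, 1321 of them shared.

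No list passed with an estimated correlation (0 of 38) or with fry (0). The estimated correlation gave adjusted p values of 0.675 for interferon, immediate early, oxidative phosphorylation, marginal zone, follicular, PI3K, transcription factor and T cell lists. It gave 0.688 for germinal centre and 0.694 for cell cycle and MYC. The lists at 0.675 were tied by the adjustment. Their unadjusted camera p values were 0.0493 (interferon), 0.0547 (immediate early), 0.0572 (T cell) and 0.146 (transcription factors). The others were 0.157 (PI3K), 0.163 (oxidative phosphorylation), 0.205 (follicular) and 0.231 (marginal zone). Fry gave adjusted p values of 0.087 for interferon and T cell, 0.0991 for immediate early, oxidative phosphorylation and PI3K, and 0.114 for transcription factors. It gave 0.174 for marginal zone, 0.219 for follicular, 0.266 for germinal centre, 0.335 for MYC and 0.38 for cell cycle. Both tests allow for the correlation within a list as these 6 libraries show it, and fry sets a list against no change and not against other genes. Follicular markers also missed under robust moderation (median -0.4196) and T cell markers at a mean of at least 50 (-0.788, Lck alone). Lists ended by the follicular score had medians of -0.0641 (follicular), -0.0855 (PI3K), -0.372 (germinal centre), -0.0589 (transcription factors) and 0.0308 (MYC), and by removal of the length trend -0.0815 (PI3K) and -0.0694 (transcription factors). Without one library the medians ran from -0.587 to -0.272 (follicular), -0.915 to -0.490 (germinal centre), -0.150 to -0.0771 (transcription factors), 0.126 to 0.324 (cell cycle) and -0.00657 to 0.146 (MYC). Apart from these constructions, the cause was not tested.

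Apart from the median of the MYC list without cKO replicate 1, whose camera direction stayed up, reversals concerned genes and lists that did not pass. Csnk2a2 gave -0.00568 rescaled without immunoglobulin genes and -0.0186 to 0.0376 without one library, mt-Co1 -0.0206 with quantile scaling, and mt-Nd5 -0.0186 with the length trend removed and -0.00355 to 0.0496 without one library. With the follicular score Lyz2 gave -0.0346, Adgre1 0.0505 and Itgb3 0.0637. Adgre1 gave 0.00137 with sample weights, and Csf3r 0.211 with edgeR and 0.200 with DESeq2. Leaving out one library gave -0.220 to 0.397 for Ccl5, -0.156 to 0.280 for Lyz2, -0.133 to 0.0536 for Adgre1, -0.596 to 0.381 for Csf3r, -1.33 to 0.117 for S100a9, -1.26 to 0.765 for Hbb-bs, -1.07 to 0.981 for Hba-a1, -1.03 to 1.003 for Hba-a2 and -0.00402 to 0.158 for Pecam1.

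The camera direction of 10 lists that did not pass turned in some fits, with these medians. Immunoglobulin constant genes gave 0.0015 under robust moderation and 0.0458 with the follicular score. The unfolded protein response gave 0.0313 with sample weights, 0.0351 with the block, 0.0357 with the length trend removed and -0.0271 with the follicular score. Heat shock genes gave 0.0236 at a mean of at least 50, 0.0355 with quantiles, -0.0118 with the trend removed, -0.0078 with the score, 0.00284 with edgeR and -0.00275 with DESeq2. Wnt genes gave 0.0232 with quantiles, 0.0463 with the trend removed and 0.0637 with the score. Dendritic cell markers gave 0.0590 with no filter, -0.126 at a mean of at least 50, -0.0139 with quantiles, -0.0477 without immunoglobulin genes, 0.0211 with edgeR and 0.0139 with DESeq2. Neutrophil markers gave -0.136 with TMM, -0.491 with sample weights, -0.137 with the block, -0.138 with the trend removed and -0.190 with the score, and could not be tested at a mean of at least 50. Erythroid markers gave -0.107 with a pseudocount of 5, -0.316 at a mean of at least 50, -0.0841 with TMM, -0.0802 with quantiles, -0.0852 with the block, -0.0576 with the trend removed, -0.418 with the score, -0.241 with edgeR and -0.268 with DESeq2, and platelet markers 0.0912 at a mean of at least 50. Fry, at an adjusted p of 0.998, turned the unfolded protein response, dendritic, neutrophil and erythroid lists. Without one library the medians ran from -0.0779 to 0.0568 (immunoglobulin), -0.0556 to 0.0834 (unfolded protein response), -0.102 to 0.198 (heat shock), -0.0921 to 0.0307 (Wnt), -0.216 to 0.0681 (NK), -0.259 to 0.0870 (dendritic), -0.691 to 0.418 (neutrophil), -0.954 to 0.820 (erythroid), -0.281 to 0.0817 (platelet) and -0.00402 to 0.158 (stromal).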

Other observations

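The tests on Csnk2a1, the test of an isolation response and the fits with a length trend removed or a follicular score were chosen after the results were seen. Several genes close to silent in WT were expressed in cKO. Among called genes, 16 rose at least 4-fold on the log2(value + 1) scale from a WT mean under 20 normalised reads, and 4 fell at least 4-fold to a cKO mean under 20. Beside Flnc, Prox1 and Heyl the first set holds Robo1, a guidance receptor gene (10.6 ± 4.71 to 71.8 ± 7.31), Slc5a5, the sodium-iodide symporter gene (1.42 ± 1.61 to 30.6 ± 4.28), Syde2 (3.42 ± 1.37 to 26.6 ± 3.98) and Eid2 (4.52 ± 0.69 to 36.7 ± 4.59). Six5, which lies next to Dmpk and Dmwd in the annotation, went from 5.12 ± 2.55 to 27.2 ± 8.85 (log2 difference 2.26 ± 0.45, adjusted p = 0.0129). All 3 neighbours rose by similar amounts on that scale, but they did not vary together across the cKO libraries. Dmwd and Dmpk were highest in cKO replicate 2 (514 and 300), where Six5 had its lowest cKO value (18.0). Robo1, Slc5a5, Syde2, Eid2 and Six5 were chosen after their values were seen.

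Variable segments were in no fixed list and were counted gene by gene. Of 98 measured Igkv segments 14 fell and 5 rose, of 96 Ighv segments 4 fell and 3 rose, and of 3 Iglv segments Iglv1 (0.35 ± 0.07) and Iglv2 (0.37 ± 0.09) rose and Iglv3 (-0.41 ± 0.06) fell. Examples of each direction, chosen after their values were seen, were Igkv8-24 at -0.73 ± 0.08 (adjusted p = 0.000453) and Igkv1-88 at 1.12 ± 0.19 (adjusted p = 0.00725). Related segments share reads, so these values are uncertain.

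The count of 1494 genes stands against 0 for the highest of the other splits: 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

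Csnk2a1 was not lower in the libraries labelled cKO. In the correlations across genes, 0 libraries were closer to the other group than to their own. This argues against a single library with the wrong label only if genotype drives the separation of the groups. No batch is given, so a library of the wrong genotype that was handled with its labelled group could also give this result. An exchange of the groups as a whole, with a deletion that takes away at least 50% of the gene's reads, would put Csnk2a1 at least 1 log2 unit higher in cKO, but the upper 95% bound of its difference was 0.143, so an exchange stays open only with a loss of reads within the interval's upper ratio of 1.104. Correct labels are bounded in the same way, by a fall of at most 5.33%, so the level does not tell exchanged labels from correct ones. A deletion of part of the gene that leaves most of the transcript countable may account for the level and cannot be told apart from an intact gene here, since a fall of at most 5.33% fits the interval and gene-level counts do not resolve exons.

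Immediate early genes were lower in cKO. Scaling is argued against as the cause: across the TMM, quantile and immunoglobulin-free scalings the list median closest to 0 was -0.5617. A length or GC trend is also argued against, with a median of -0.5577 after its removal. A different stress response to cell isolation could lower the same genes, and the heat shock list had a median of 0.0238 over members that went both ways, so it cannot be told apart from an effect of the genotype, with no sorting day or order in the labels. Without WT replicate 1, the highest WT library for 19 of the 20 heat shock genes, that list rose (median 0.198, adjusted p = 0.000203, range 0.000203 to 0.998) and the immediate early median was -0.5086, but this rests on leaving out that library and on the preset correlation (adjusted p = 0.999 for the heat shock list of all 6 libraries with an estimated correlation), so it decides nothing.

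Marginal zone markers were higher and follicular markers lower in cKO, which fewer follicular B cells in the sorted cells could produce. With the follicular score as a covariate, the median log2 difference of the 6 called marginal zone markers went from 0.50 to 0.4241 (median SE 0.086 in both fits) with 5 of them past the threshold, and that of all 15 from 0.16 to 0.0822, where the list still passed (adjusted p = 0.0223, range 2.81e-07 to 0.0223, at the preset correlation; without the score, adjusted p = 0.675 with an estimated correlation and 0.174 with fry). The 6 stayed above the bound set for them, but they were chosen by their calls in these same libraries, and the score rests on 2 genes. A lower follicular share therefore cannot be told apart from an effect of the genotype here. The fit shows only that 5 of the 6 differed beyond what the score took up. A length trend is argued against. After its removal the median of all 15 was 0.1469 (camera adjusted p = 0.000397 at the preset correlation), and that of the 6 called markers 0.4677, with 5 past the threshold. The 3 called follicular markers, none of them in the score, went from -0.48 (median SE 0.093) to -0.2539 (0.084) and 1 passed, while the median of all 7, which include Fcer2a and Ighd of the score, went from -0.42 to -0.0641 and the list lost its call (adjusted p = 0.285, range 1.15e-05 to 0.285), with smaller differences and a degree of freedom fewer. The 3 called members stayed below the bound set for them, but they too were chosen by their calls. The median of the whole list came close to 0 in part because the score holds 2 of its genes, so it decides nothing. For the follicular markers, too, a lower follicular share cannot be told apart from an effect of the genotype.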
